A study of Drosophila melanogaster with 3 samples.

How the data were processed

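Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole prepupae of Drosophila melanogaster of both sexes, pooled. Per the labels, the flies carried a transgene for Blimp-1, a zinc finger transcription repressor, fused at its C terminus to green fluorescent protein (GFP), and chromatin was sheared by sonication and precipitated with an antibody against GFP. The labels give 3 biological replicates of 1 group, so the series holds no comparison between groups and no treated or control group. A control experiment is named in the labels as possible, and it was not analysed here.

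The authors deposited peak lists in the narrowPeak layout on 2 genome builds, dm6 and dm3. The text deposited with each library describes, for each build, a relaxed list of peaks and background for every replicate, a relaxed list for the pooled replicates, and a list thresholded on the irreproducible discovery rate (IDR), which scores how well peak ranks repeat between replicates. Each relaxed list holds 30000 peaks, and its length is therefore a limit of the list and not a measure of the library. The aligner, the peak caller and their settings are not given in the sources used here. Column 7 of the deposited lists was read as the peak caller's signal per peak, whose scaling is not given in the sources used here, so signal was used only to rank peaks and to set a peak against the median site of the same list. Column 9 of the deposited lists was read as −log10 of a q-value, which stood at its highest value of 3.96 for 82.2% of the reproducible dm6 peaks and was therefore not used for ranking. Column 10 of the deposited lists was read as the distance of the summit from the start of the peak. The same text lists, for the relaxed lists of a build, 1 further parent file shared by all replicates, whose role is not stated. The deposited lists carry no read counts, so the depth of each library is unknown and no interval from read counting can be given.

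All results used the dm6 lists unless dm3 is named. Overlapping IDR peaks were merged, with the summit of the strongest peak kept, and the merged regions are called reproducible sites. All 5573 IDR peaks on dm6 were the 5573 strongest peaks of the pooled relaxed list, with a lowest signal of 205. The signal of a site in a replicate was that of its strongest overlapping peak in that replicate's relaxed list, divided by the replicate's median over all reproducible sites, and is called relative signal. Its mean and SD were taken over the replicates with a peak at the site. Peak lists of replicates were compared by an overlap of at least 1 bp, using as many of the strongest peaks of each replicate as there were reproducible sites.

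Gene positions and transcription start sites (TSSs) came from the Ensembl release 115 annotation of genome release 6 (FlyBase 6.54), the assembly known as dm6. A gene counted as bound when a reproducible summit lay within 1000 bp of one of its annotated TSSs, and such a site is called a promoter site. Sites farther from any protein-coding TSS are called distal. Coordinates are on dm6 and counted from 1. The share of promoter sites was compared with the share of the major chromosome arms lying within 1000 bp of a TSS by a two-sided exact binomial test, and with pooled relaxed regions outside the reproducible sites by Fisher's exact test.

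Bound genes were tested in 29 gene lists by two-sided Fisher's exact tests, each against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 29 lists. Motif centring compared the share of summits with a motif within 100 bp with that in windows of the same size centred 500 bp away, by a two-sided exact McNemar test on the flank at higher coordinates. The main motif was GTGAAAG, the core of the PRDI-BF1 (Blimp-1) consensus, and 12 further motifs were adjusted with it as 1 family of 13. All 2080 6-mers, with both strands joined, were tested between summit and flank windows by Fisher's exact test with Benjamini-Hochberg adjustment. The share of sites on X was tested against the share of X in the length of the major arms by a two-sided exact binomial test. Genes and sites are the units of these tests, not animals, and neighbouring genes can share a site, so p-values describe these lists. Replicate means and SDs (n = 3) are given beside them.

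Genes were named by a rule written before the data were examined. It took every member of the ecdysone regulator list, the nearest protein-coding gene of the 10 strongest sites, up to 3 bound members with the highest signal for every other list past an adjusted p of 0.05, and the 5 most enriched k-mers. Other lists are given as counts. The nearest gene is not reported for every named site. Symbols rtz and ma of the gene lists matched no gene of the annotation. Alternatives to each choice, including leaving out each replicate in turn, were also fixed before the data were examined, apart from the tRNA comparison with single-TSS genes and the ranking of the strongest sites without each replicate. A comparison of sites missing from replicate 3 with the lowest relative signal of its list, tried after the values had been seen, was dropped, since at least 98.3% of missing and 99.3% of present sites lay above it in replicates 1 and 2.

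The tests were tried on simulated data with known answers. In 20 runs over 13945 genes, a raised bound share was recovered for the signalling list in 95% of runs, for the proteasome list in 100% and for the ecdysone regulator list in 95%, and 0.385% of tests of unchanged lists were called. In these runs each gene was bound independently, and at an equal rate outside the raised lists. In the data, genes differ in length and number of TSSs, and neighbours can share a site. False calls from such differences were therefore not tested. GTGAAAG planted at 10% of 4990 simulated sites raised its share by 9.54 percentage points with p = 3.07e-77 (exact McNemar test). With GTGAAAG planted, 7 of 2080 6-mers were called and the 2 that make it up ranked first, and 0 were called with nothing planted. The simulated summit and flank windows were shuffled sequences of the same base composition. False calls from a difference in composition between real summits and flanks were therefore not tested. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.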

Results

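Blimp-1 is a zinc finger repressor whose gene is induced by the steroid hormone ecdysone at the onset of metamorphosis, and it is known for setting the timing of ftz-f1 expression in prepupae. Its binding was mapped by anti-GFP ChIP-seq in 3 biological replicates of whole prepupae carrying Blimp-1-GFP. The authors' IDR list on dm6 held 5573 peaks, which merged to 4990 reproducible sites. The deposited signal of these peaks ran from 205 to 10091 with a median of 359. The depth of the libraries is unknown, since the lists carry no read counts.

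The strongest binding lay at a small set of genes that included Blimp-1 itself. The site of highest deposited signal, 10091, lay on chromosome 3R from 9057249 to 9058029 in intron sequence, 4414 bp downstream of the nearest TSS of Kdm2, which encodes a histone lysine demethylase. Its relative signal was 25.7 ± 3.49 times the median site (SD, n = 3). The sites ranked 2 and 4 were both intergenic and upstream of Blimp-1 on chromosome 3L. One, from 5627561 to 5628489, had its summit 3029 bp from the nearest Blimp-1 TSS and a relative signal of 24.5 ± 6.16 (SD, n = 3), and the other, from 5621688 to 5622683, had its summit 8796 bp away and a relative signal of 19.2 ± 3.503 (SD, n = 3).

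The other 7 of the 10 strongest sites were each nearest to a different gene. A site in intron sequence on chromosome 2L from 14995385 to 14996384, 1804 bp downstream of a TSS of mol, which encodes a maturation factor of dual oxidase, reached 23.6 ± 2.38 times the median site (SD, n = 3). Sites in 5′ UTRs lay 5 bp downstream of the TSS of GstE13, a glutathione S-transferase gene on chromosome 2R (9121842 to 9122462), and 248 bp downstream of that of Aldh-III, an aldehyde dehydrogenase gene on the same arm (7473546 to 7474459). Their relative signals were 19.0 ± 1.24 and 16.9 ± 3.20 (SD, n = 3). A site 236 bp upstream of cu on chromosome 3R (11196937 to 11197665) reached 16.8 ± 1.34 (SD, n = 3). Intronic sites nearest to dyl, which encodes a zona pellucida domain protein of the apical cell surface (chromosome 3L, 4304029 to 4305210), and to CG12159 (chromosome 2R, 7909265 to 7910028) reached 15.9 ± 2.16 and 14.9 ± 1.16 (SD, n = 3). Their summits lay 3303 and 6825 bp downstream of the nearest TSS. The site ranked 10, on chromosome 3L from 17577446 to 17578375, lay in an intron 1323 bp upstream of a TSS of Eip74EF, an ecdysone-induced ETS factor gene, at 13.8 ± 1.85 (SD, n = 3). When sites were ranked on the remaining replicates with each replicate left out in turn, 9 or 10 of these 10 sites stayed among the 10 strongest.

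**Figure D1:**
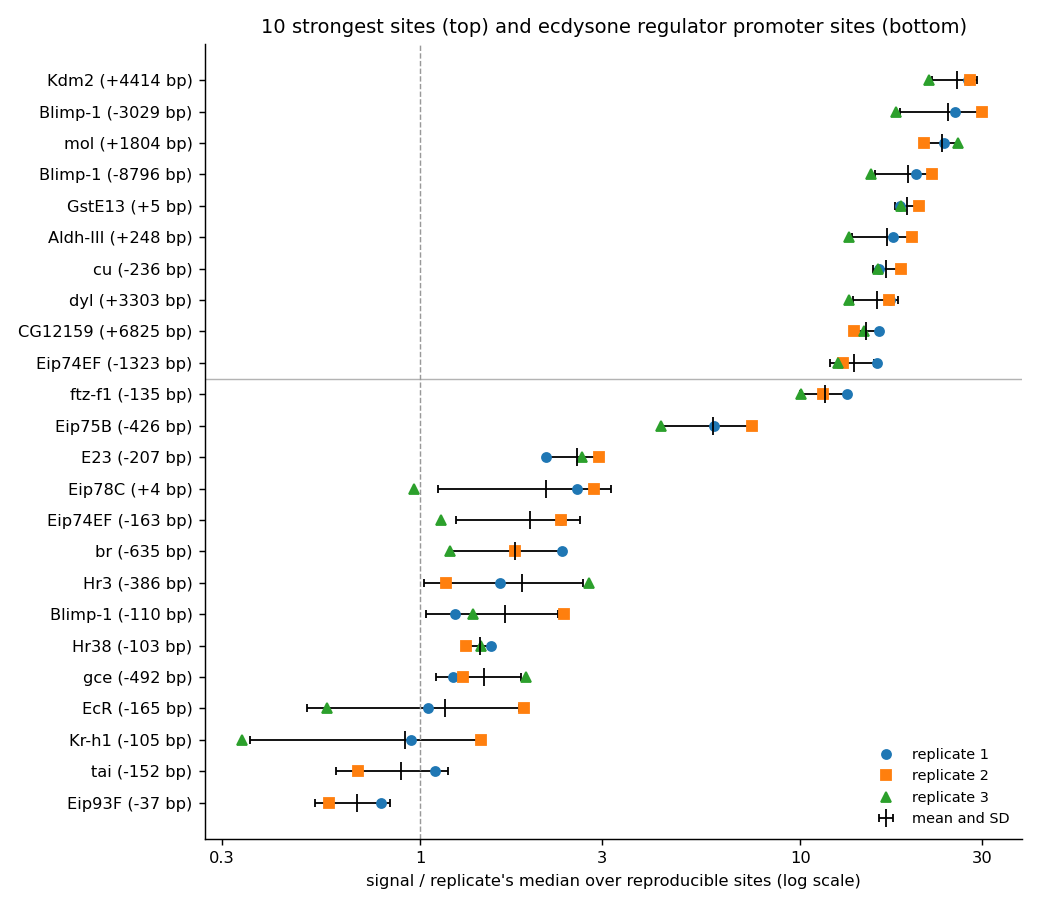
Relative signal (signal divided by the replicate's median over reproducible sites, log axis) at the 10 strongest sites, named by nearest protein-coding gene, and at the promoter sites of ecdysone regulators, with the distance of each summit from the TSS in bp; points are the 3 replicates, ticks and bars the mean and SD. The ftz-f1 promoter site, at 11.6, stands above the other ecdysone regulator promoter sites, and tai and Eip93F have no peak in replicate 3.

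Genes of ecdysone regulators were bound far more often than other genes. Of 19 ecdysone regulators, 14 had a promoter site (73.7%), against 18.6% of the 13926 other protein-coding genes. The share was 68.4% ± 5.26 over the replicates (SD, n = 3). The strongest of these sites within 1000 bp of a TSS lay at ftz-f1, a nuclear receptor gene, on chromosome 3L from 18765570 to 18766234, with its summit in an intron 135 bp upstream of an internal TSS. Its relative signal was 11.6 ± 1.60 (SD, n = 3) and it ranked 20 among all sites. The odds ratio for the list was 12.2 with an adjusted p of 2.69e-06 (Fisher's exact test, Benjamini-Hochberg). Many of these genes are long and have several TSSs: in 10000 random lists matched on both, 7.40 bound genes were the mean, and the adjusted p was 0.0202 (permutation test on matched lists).

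Other ecdysone regulators also carried promoter sites. The site of Eip75B, a nuclear receptor gene, on chromosome 3L from 18061634 to 18062116, reached 5.88 ± 1.58 times the median site (SD, n = 3). Those of E23, which encodes an ABC transporter, and Eip78C, a nuclear receptor gene, reached 2.58 ± 0.41 and 2.14 ± 1.03 (SD, n = 3). The promoter sites of Eip74EF (1.94 ± 0.70), Hr3 (1.85 ± 0.83), br (1.77 ± 0.58), Blimp-1 (1.67 ± 0.63), gce (1.47 ± 0.37), Hr38 (1.43 ± 0.11), EcR (1.16 ± 0.66) and Kr-h1 (0.91 ± 0.55) lay between 0.91 and 1.94 times the median site (SD, n = 3). The Hr3 site lay nearer to a TSS of Hdc. The promoter sites of tai (0.89 ± 0.29) and Eip93F (0.68 ± 0.15) had a peak in replicates 1 and 2 (SD, n = 2), which for Eip93F was among the strongest peaks of 1 replicate. With sites supported by all 3 replicates alone, tai, Eip93F and Kr-h1 had no promoter site.

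Several ecdysone regulators had stronger sites inside the gene, or farther upstream, than within 1000 bp of a TSS. Sites in the gene body or up to 2000 bp upstream numbered 28 at Eip75B, 12 at ftz-f1, 12 at Hr4, 11 at EcR and 11 at Eip74EF. An intronic Eip75B site on chromosome 3L from 17968371 to 17969113 reached 11.3 ± 2.21, and an intergenic site upstream of Hr38 on chromosome 2L from 20715927 to 20716653 reached 12.7 ± 1.73 (SD, n = 3). Intronic sites reached 9.15 ± 2.14 in Kr-h1 (chromosome 2L, 6088305 to 6089013), 8.98 ± 1.83 in Hr4 (chromosome X, 1972065 to 1972763), 6.43 ± 1.06 in E23 and 6.23 ± 1.51 in EcR (SD, n = 3). Hr4, crol and Hr39 had no promoter site, but 12, 2 and 1 sites in the gene body or up to 2000 bp upstream. Met, which encodes a juvenile hormone receptor, and usp, which encodes the partner of the ecdysone receptor, had 0, and their nearest summits lay 6234 and 4405 bp from a TSS.

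**Figure D2:**
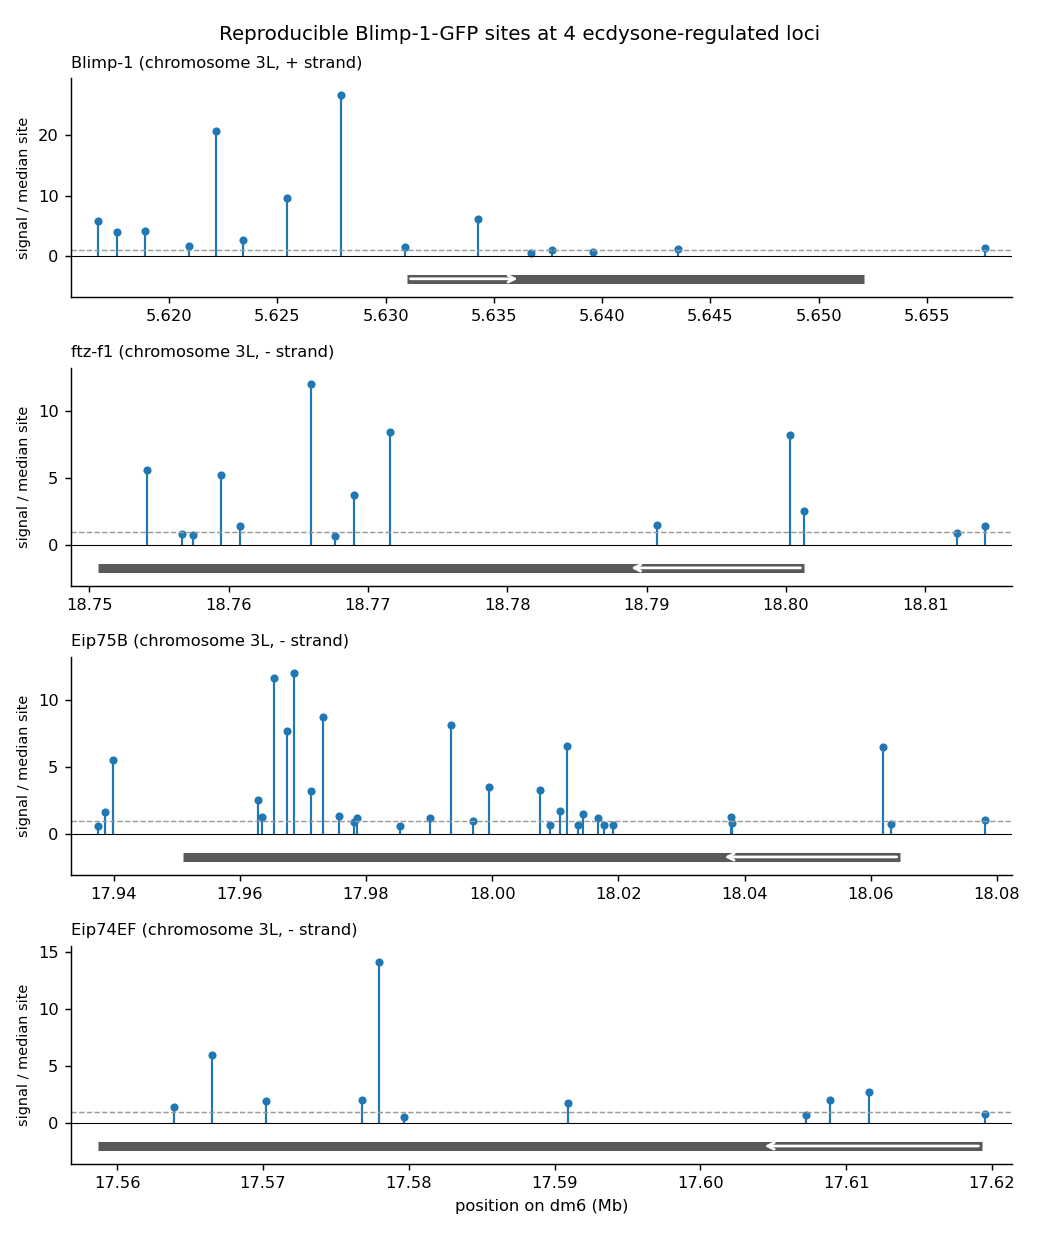
Reproducible sites at Blimp-1, ftz-f1, Eip75B and Eip74EF on chromosome 3L of dm6; each stem is a site summit, its height the deposited signal divided by that of the median site (dashed line at 1), the grey bar the annotated gene and the white arrow the direction of transcription. The tallest stems at Blimp-1 stand upstream of the gene, at 26.7 and 20.7, and the tallest at ftz-f1, at 12.1, inside it.

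Outside the ecdysone regulators, ribosomal protein genes stood out. Of 88 genes for cytoplasmic ribosomal proteins, 60 had a promoter site (68.2%), against 18.4% of other genes. The strongest site lay at RpL36A, at 11.0 ± 2.31 times the median site, followed by RpS28a at 6.78 ± 1.78 and RpS28b at 2.99 ± 0.24 (SD, n = 3). The RpS28a and RpS28b sites lay nearer to the TSSs of Mgat2 and l(1)G0320. The list's odds ratio was 9.52 with an adjusted p of 9.29e-23 (Fisher's exact test, Benjamini-Hochberg). The bound share was 69.3% in replicate 1 and 67.05% in replicate 2, but 38.6% in replicate 3.

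Members of signalling pathways and of cell death were bound more often than other genes, with less certainty. Of 31 members of the Notch, EGF, Wnt, Hedgehog, BMP, Hippo and JAK-STAT pathways, 17 had a promoter site (54.8%), among them spi, which encodes an EGF receptor ligand (3.21 ± 0.44), ds, a cadherin gene of the Hippo pathway (2.66 ± 0.57), and brk, a repressor gene of the BMP pathway (2.00 ± 1.05; SD, n = 3). Of 21 cell death and autophagy genes, 10 had one (47.6%), among them the death activators hid (2.84 ± 0.67) and rpr (1.95 ± 0.68) and the autophagy gene Atg17 (1.75 ± 0.64; SD, n = 3), whose site lay nearer to Xe7. Adjusted p was 5.20e-05 for signalling and 0.0139 for cell death (Fisher's exact test, Benjamini-Hochberg). The threshold was missed in 3 of 10 alternatives for signalling, where adjusted p ranged from 5.93e-06 to 0.140, and in 7 of 10 for cell death, where it ranged from 0.00579 to 0.217.

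Genes for chemoreceptors and digestive enzymes were seldom bound. Of 179 chemoreceptor genes, 6 had a promoter site (3.35%), with Ir52a at 2.65 ± 0.80, Or67a at 1.67 ± 0.79 and Ir94h at 1.63 ± 0.21 as the strongest (SD, n = 3). Of 51 odorant binding protein genes, 2 had one, Obp56i (3.33 ± 0.97) and Obp83g (0.84 ± 0.10; SD, n = 3), and of 35 digestive enzyme genes 1, Mal-A5 (2.25 ± 0.32; SD, n = 3). Proteasome subunit genes, although active in every cell, were also seldom bound, with 2 of 48, Rpn5 (1.12 ± 0.01) and Prosalpha6 (0.93 ± 0.25; SD, n = 2), whose sites lay nearer to Hat1 and Npc1a. The adjusted p was 1.22e-08 for chemoreceptors, 0.0168 for odorant binding proteins, 0.0332 for the proteasome and 0.0467 for digestive enzymes (Fisher's exact test, Benjamini-Hochberg). Chemoreceptors stayed past the threshold in 10 of 10 alternatives, odorant binding proteins in 1, digestive enzymes in 1 and the proteasome in 3, with adjusted p up to 0.563, 0.460 and 0.326.

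Among 290 tRNA genes, 38 had a site within 1000 bp (13.1%; adjusted p = 0.0467, Fisher's exact test, Benjamini-Hochberg). A pair of neighbouring tRNA genes for tyrosine shared the strongest such site, at 2.42 ± 0.24 times the median site, and a tRNA gene for glutamine had the next, at 1.91 ± 0.15 (SD, n = 3). Against the 10246 protein-coding genes with a single TSS, of which 13.4% were bound, no difference was detected (p = 1, Fisher's exact test). The list stayed below other genes and past the threshold in 6 of 9 alternatives, with adjusted p up to 1, and 0.000444 within 500 bp (Fisher's exact tests). Among the 6, the alternative with the nearest TSS alone carries no weight. Only protein-coding TSSs counted there, so no tRNA gene could be bound.

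The other 20 lists did not pass the threshold. For tissues and processes of metamorphosis, the bound genes were 14 of 123 for cuticle proteins, 10 of 31 for chitin and tanning, 4 of 16 for ecdysteroid metabolism, 5 of 20 for late ecdysone-responsive genes, 0 of 11 for salivary glue proteins, 4 of 16 for trachea and 5 of 24 for imaginal disc patterning. For other cell types, they were 3 of 20 for muscle, 2 of 18 for neurons, 6 of 16 for fat body, 1 of 14 for hemocytes, 2 of 21 for photoreceptors and 0 of 19 for testis. The remaining counts were 3 of 27 for antimicrobial genes, 5 of 22 for segmentation, 0 of 8 for Hox genes, 6 of 15 for the Enhancer of split and Bearded complexes, 5 of 19 for insulin and growth, 4 of 8 for the circadian clock and 7 of 23 for heat shock. The Enhancer of split and Bearded list passed the threshold against matched random lists (adjusted p = 0.0182, permutation test).

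**Figure D3:**
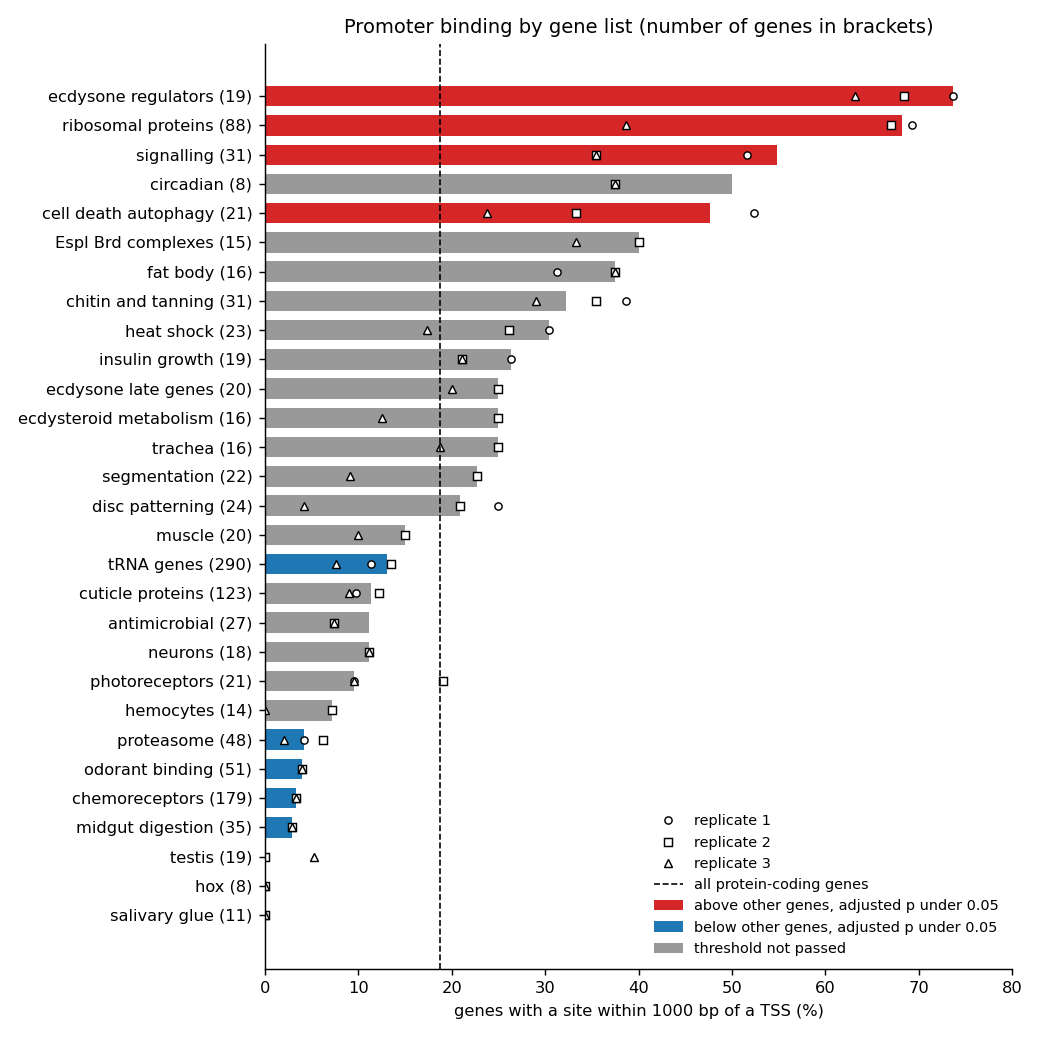
Share of genes with a site within 1000 bp of a TSS for each of the 29 gene lists, with the number of genes in brackets; bars are the reproducible sites, open symbols the 3 replicates' strongest peaks, and the dashed line all protein-coding genes (18.7%). Ecdysone regulators (73.7%) and ribosomal proteins (68.2%) have the longest bars, and replicate 3 lies below the other replicates for ribosomal proteins.

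The recognition sequence of Blimp-1 was centred on the sites. GTGAAAG lay within 100 bp of the summit at 8.50% of sites, against 2.79% of flank windows, a ratio of 3.05 (over replicates 3.05 ± 0.55, SD, n = 3; p = 4.21e-37, exact McNemar test). The full consensus MAGYGAAAGYK, in which M, Y and K each stand for a pair of bases, was found at 3.69% of summits and 0.391% of flanks, a ratio of 9.44. Counted after the data had been examined, a match with at most 1 mismatch lay at 22.1% of summits and 6.81% of flanks. Stronger sites carried the consensus more often: it was present at 6.17% of the sites in the highest signal quartile and 2.40% of those in the lowest (odds ratio 2.67, adjusted p = 1.38e-05, Fisher's exact test). Distal sites (3.83%) and promoter sites (3.52%) did not differ detectably (adjusted p = 0.598, Fisher's exact test), whereas the shorter GAAAG was at 57.1% of distal and 53.3% of promoter sites (adjusted p = 0.0127, Fisher's exact test).

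Examples of the sequence stood at named sites. The RpL36A site holds AAGTGAAAGTG on chromosome 2L at 8043369 to 8043379, 16 bp from the summit, and the Ir52a site holds CAGCGAAAGTT on the minus strand of chromosome 2R at 15498819 to 15498829, both full matches. Of the 10 strongest sites, 0 had a full match, 5 had one with at most 1 mismatch, and 9 one with at most 2, which was also present at 65.9% of all summits and 50.1% of flanks. At the Kdm2 site the closest sequence was AAGTGAAGGCG (chromosome 3R, 9057710 to 9057720) and at the Eip74EF site AAGTGAAAATT (minus strand of chromosome 3L, 17577971 to 17577981), each with 1 mismatch.

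**Figure D4:**
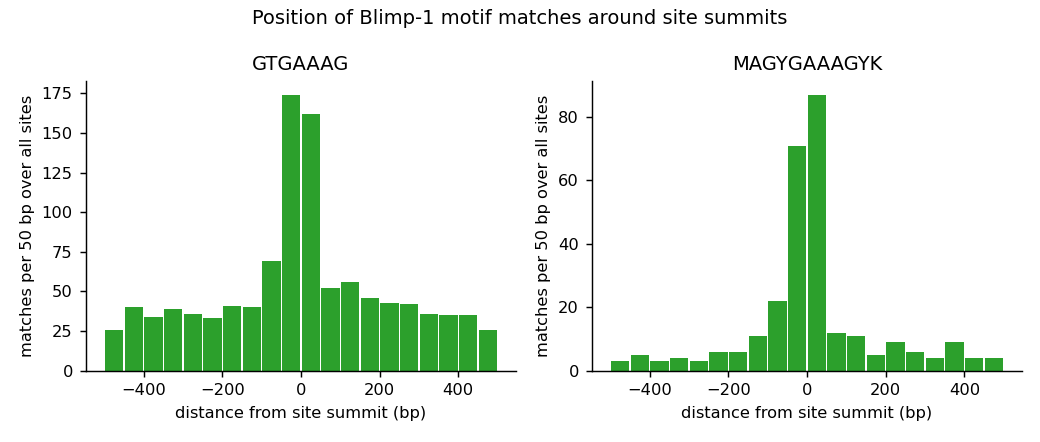
Number of matches to GTGAAAG (left) and to MAGYGAAAGYK (right) per 50 bp, by distance in bp from the summits of all 4990 sites. Matches peak within 50 bp of the summit, at 174 and 162 for GTGAAAG and 71 and 87 for the full consensus.

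Of the 12 other motifs, 3 that belong to general promoter or chromatin factors were also centred. The GAGA factor motif lay at 8.14% of summits and 4.41% of flanks (adjusted p = 1.23e-14, exact McNemar test with Benjamini-Hochberg adjustment). Its ratio was 1.85, and ranged from 1.15 to 2.19 over the replicates. Motif 1 had a ratio of 2.71 (adjusted p = 0.00694) and the DNA replication-related element 1.29 (adjusted p = 0.0101, exact McNemar tests with Benjamini-Hochberg adjustment), the last of which was not detected against the flank at lower coordinates (p = 0.105, exact McNemar test). The shorter GAAAG core was present at 55.4% of summits and 39.0% of flanks. The CA repeat and the motifs of Zelda, grainy head, nuclear receptor monomers, E-boxes, POU factors and STAT did not pass the threshold. Against the flank at lower coordinates, unadjusted p was 0.00573 for grainy head (ratio 1.52 over both flanks), 0.0132 for STAT (0.851) and 0.0431 for E-boxes (0.788; exact McNemar tests).

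A search without a preset motif returned the same sequence. Of 2080 6-mers, 298 were enriched at summits and 582 depleted, and all 8 that contain GAAAG were enriched. These counts were not adjusted for base composition, with G or C at 39.9% of summit and 42.2% of flank positions. The most enriched was GAAAGT (28.3% of summits, 12.6% of flanks, odds ratio 2.74). Next came AGTGAA (odds ratio 2.17), AAGTGA (2.09), TGAAAG (2.02) and CGAAAG (2.00), each a part of the consensus. Adjusted p for these 5 ranged from 1.25e-114 to 8.53e-45 (Fisher's exact test, Benjamini-Hochberg).

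Sites were concentrated at promoters. Of the 4990 sites, 2303 were promoter sites (46.2%, 95% Wilson interval 44.8 to 47.5), against 20.3% of the major arms, and the exact binomial p was too small for the software to represent. Among 18228 weaker pooled regions outside the reproducible sites, 27.7% were at promoters (odds ratio 2.24, p = 9.34e-131, Fisher's exact test). Away from promoters, introns held 35.2% of sites and 36.3% of the genome, intergenic sequence 17.3% and 28.3%, and coding sequence 0.421% and 10.2%. The promoter share of the strongest peaks was 49.5% in replicate 1, 47.6% in replicate 2 and 38.7% in replicate 3, with a mean of 45.3% ± 5.75 (SD, n = 3).

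The arms were bound at similar densities except chromosome 4 and 3L. Chromosome 4, a small and largely heterochromatic chromosome, had 11 sites, or 8.16 per Mb (p = 3.83e-11, exact binomial test), and its density over replicates was 4.95 ± 1.13 per Mb (SD, n = 3). Arm 3L had 41.1 sites per Mb (p = 0.000228, exact binomial test), and 2L, 2R and 3R had 35.5, 37.8 and 37.0. X, present at a lower copy number in males, held 16.9% of sites and 17.6% of the length, a difference that was not detected (p = 0.234, exact binomial test).

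Replicates shared most but not all sites. Among the 4990 sites, 82.7% were overlapped by the strongest peaks of replicate 1, 81.6% by those of replicate 2 and 73.7% by those of replicate 3, a mean of 79.4% ± 4.93 (SD, n = 3). All 3 replicates supported 2837 sites (56.9%), exactly 2 supported 1310, exactly 1 supported 750, and 93 had support from 0. After random shifts, all 3 supported 1.53%. The sites were called from these same replicates, so high overlap was in part built in. The random shifts are therefore no test of reproducibility. Even in the relaxed lists, 589 sites had no peak in replicate 3, against 2 in replicate 1 and 35 in replicate 2. Spearman's rho of signal was 0.83 between replicates 1 and 2 (4953 sites), 0.74 between 1 and 3 (4400), and 0.62 between 2 and 3 (4375). It was taken across sites with a peak in both replicates, so sites missing from replicate 3 were left out of its pairs. Sites are not independent replicates.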

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

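The choice of signal threshold and of the replicates required set the number of sites. Some other changes had a direction fixed by the measure, as stated, and the cause of the rest was not tested. The tRNA comparison with single-TSS genes and the ranking of the strongest sites without each replicate were chosen after seeing the data. The 4990 sites became 2495 at or above the median signal, 2837 with support from all 3 replicates, and 3035 to 3593 with support from the remaining replicates when each was left out. The left-out replicate still helped to call these sites. For results on sites and genes, leaving it out therefore cannot be told apart from keeping fewer sites. Full support, 56.9%, became 34.7% with a reciprocal overlap of 50%, 50.9% with summits within 100 bp, 30.5% with fewer of the strongest peaks (0.5 times the number), 82.7% with more (2 times), and 60.8% to 72.0% with each replicate left out. It can only fall with a larger overlap required or fewer peaks, and only rise with more peaks or fewer replicates required. The direction of these changes was therefore fixed in advance. The mean rho of 0.73 became 0.62 to 0.83, lowest without replicate 1. Enriched k-mers rose from 298 to 503 with 7-mers, where more sequences were tested. The 4 gene lists above other genes became 2 at or above the median signal, 2 with support from all 3 replicates, and 2 to 3 with each replicate left out. They became 5 within 2000 bp of a TSS, against random lists matched on number of TSSs and gene length, and with the nearest TSS alone. Without replicate 1, 2 were above, and ecdysone regulators and ribosomal proteins were past the threshold in each of 10 alternatives, with adjusted p up to 0.0202 and 0.0028. For tRNA genes, the log2 odds ratio turned to 0.0438 within 2000 bp of a TSS. The share of sites on X turned from below its share of length to above it at or above the median signal (17.9%), with support from all 3 replicates (18.5%), and with each replicate left out (17.7% to 18.4%), and missed the threshold in each. The named promoter sites also depended on the distance to the TSS, and on the deposited signal over that of the median site ftz-f1, at 12.1, ranked highest among ecdysone regulators at 1000 bp. Within 2000 bp, sites of Eip74EF (14.2) and Hr38 (13.6) exceeded it, the values of Eip75B, Blimp-1, Eip78C and tai rose to 8.73, 6.21, 2.76 and 1.41, and crol (1.08) and Hr4 (1.21) gained a site. Within 500 bp, ds, brk, RpS28a, Ir52a, Ir94h, Obp56i and a tRNA gene for tyrosine had no site, and RpS28b fell from 3.14 to 1.33 and br from 1.80 to 0.964. With support from all 3 replicates, tai, Eip93F, Kr-h1, Rpn5 and Prosalpha6 had none. The promoter share and the centring of GTGAAAG kept their direction and their side of the threshold in all 8 and all 10 alternatives run, with ratios from 1.42 for GAAAG to 9.44 for the full consensus. X was not tested on dm3, since its chromosome lengths were not used here, and no paired analysis was possible because there is 1 group.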

Other observations

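Of the tests below, the comparison of ribosomal protein with proteasome genes, the tests of site signal as the whole cause of missing sites and of extra copies as the whole cause of strong Blimp-1 sites, and the counts by gene symbol were chosen after the results had been seen.

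Ecdysone regulators were also bound more often over the gene body and 2000 bp upstream, where 17 of the 19 held a site, against a mean of 9.9998 in random lists matched on gene length (adjusted p = 0.0101, permutation test on matched lists). At ftz-f1, further strong sites lay on the 5′ side of the promoter site, with deposited signals of 8.44 times the median site on chromosome 3L from 18771283 to 18772012 and 8.24 from 18800054 to 18800613, 1029 bp downstream of another TSS. At Blimp-1, a further upstream site from 5625074 to 5625701 reached a deposited signal of 9.56 times the median site and an intronic one from 5633497 to 5634608 reached 6.21.

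Genes were also grouped by the start of their symbols, in families of at least 15 genes. Histone genes, most of them copies in a tandem repeat to which short reads cannot be assigned one by one, had 1 promoter site (0.870% of the family, adjusted p = 3.7e-08, Fisher's exact test), at His3.3B, a histone variant gene that lies outside the repeat. Gustatory receptor genes had 0 of 60 (adjusted p = 8.56e-05, Fisher's exact test). Genes of peroxisome biogenesis (Pex) had 7 of 15 and did not pass the threshold (adjusted p = 0.0695, Fisher's exact test).

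The first pattern weighed is the binding at ribosomal protein promoters. Signal at constitutively active promoters in general cannot be judged from proteasome genes. Fewer of them were bound than of other genes (4.17%), so constitutive activity alone did not go with binding there. This comparison was chosen after that share was known, and 1 list cannot stand for all such promoters. The difference was not detected against matched random lists (adjusted p = 0.183, permutation test on matched lists). A single replicate cannot account for the ribosomal protein binding, since the excess over other genes was at least 25.05 percentage points in every replicate. In replicate 3, 23 of the 60 ribosomal protein sites had no peak, so this pattern overlaps the third. Binding through the GTGAAAG core stays open. The core lay at 8.33% of the ribosomal protein sites and 7.76% of other promoter sites, so it was no rarer there. Most of the ribosomal protein sites lack it, however. The shorter GAAAG was more frequent at them (68.3% and 52.9%, unadjusted p = 0.0184, Fisher's exact test). For the full consensus, present at 1 of the 60 sites, no difference was detected (1.67% and 3.57%, p = 0.722, Fisher's exact test). Signal that does not depend on Blimp-1 at the most highly transcribed genes may also contribute, and no sample without the tagged protein was analysed here. With 1 group, no biological explanation was tested.

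The second pattern is the pair of strong sites upstream of Blimp-1. Extra copies from the transgene that cover the whole locus would raise its sites alike, and would not set the pair apart from the other 9 sites nearest to Blimp-1. The weaker of the pair had 13.1 times the median signal of those 9, which ran from 0.588 to 9.56 times the median site. However, the pair was picked for its strength, and the extent of the transgene was not examined here. Extra copies as the whole cause therefore cannot be judged from this ratio. Within 20 kb of Blimp-1, 14 weaker pooled regions were found, against a median of 6 around other bound genes, which places it at percentile 95.05. Up to 16 were found around other ecdysone regulators, at Eip93F, so weaker regions gathering around such genes in general would give the same count. Extra copies, as the whole cause or a part of it, and such gathering all stay open, and no biological explanation was tested.

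The third pattern is the 589 sites with no peak in replicate 3, of which 81.7% were promoter sites, against 41.4% of the sites with a peak. Within deciles of signal, distal sites were missing less often than promoter sites (odds ratio 0.137, 95% interval 0.110 to 0.171), which argues against loss of distal sites and against site signal as the whole cause. Weaker recovery of the weakest sites stays open in part. Of the missing sites, 29.7% were in the lowest signal quartile, between the bounds of 25 and 50 set beforehand. With no relation to signal, 25% would lie there. The missing share was 10.8% in the lowest decile, 18.6% in decile 4 and 1.00% in the highest. Sites were called on the pooled replicates, so those weak in replicates 1 and 2 more often needed a replicate 3 peak to be listed. This selection would lower the missing share of the weakest sites, so these shares cannot decide the question. The comparison within deciles rests on the same selected sites. Displaced peaks cannot be told apart either, since the 2.21% with a replicate 3 summit within 500 bp was nearly fixed by counting sites without overlap as missing, nor can promoter signal without the Blimp-1 consensus, since the consensus was at only 1.87% of missing and 3.95% of present promoter sites (odds ratio 0.655, 95% interval 0.317 to 1.36), while GTGAAAG was at 7.90% and 7.74%. No biological explanation was tested, and a difference in the age of the prepupae, which the labels give as unknown, stays untested.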
